A study of Danio rerio with 30 samples.

How the data were processed

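Spleen RNA of 30 zebrafish was sequenced, 5 per group in 6 groups of incubation temperature (24, 28 or 32 °C) and treatment (control or LPS). Per the labels' protocols, libraries came from poly(A)-selected RNA with a directional kit. Per the submitters' processing notes, bcl2fastq, cutadapt 1.12, FastQC 0.11.5, STAR and DESeq2 1.11.1 were used, with the GRCz11 build. The program that counted reads, the annotation and the strand setting are not given in the sources used here, so reads shared by paralogs or by overlapping or antisense genes may have been assigned to either. The values the authors deposited are whole-number counts per gene and library, not normalised, for 31901 Ensembl gene IDs. A table of names gave a symbol to 29178 of them. Many symbols are those of human orthologues, and 926 symbols were shared by 1893 tested genes, so the ID is given where a symbol is shared. Coordinates were not used here.

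The counts were analysed in R 4.3.3 with edgeR 4.0.16. Low-count genes were removed with filterByExpr, which left 17841 genes, and libraries were scaled by TMM. All 30 libraries entered one fit with a mean for each group (24 residual degrees of freedom, robust quasi-likelihood, common biological coefficient of variation 0.503). Each contrast was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment over all tested genes, with adjusted p under 0.05 as the threshold. Adjusted p values of genes in the text come from this edgeR test unless another tool is named. SEs are the log2 fold change divided by the square root of F. CPM are counts relative to the TMM-scaled library size (edgeR's cpm), with their SD over 5 libraries. Summed CPM of marker lists are instead relative to the total counts of the library, without TMM scaling.

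The contrasts were LPS against control at each temperature and on average, the differences between these responses, their joint test, and temperature against temperature within control and within LPS fish. These contrasts, the naming rule, 31 gene lists and the alternatives were fixed before the data were examined. Genes were named if they had a symbol other than a clone name, an adjusted p under 0.05 and a mean of at least 5 CPM in the higher group: up to 10 highest and 10 lowest for LPS contrasts, 8 and 8 for temperature contrasts, the 10 smallest p values for differences in response (with 5 more not past the threshold where fewer than 10 passed), up to 4 members per list and the 3 most abundant genes. Lists were matched by exact symbol and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1), adjusted over the lists of a contrast. A response score per fish was the mean log2 CPM (prior count 2) of genes called higher minus that of genes called lower in a fit of only the 10 libraries of the temperature not compared. The difference of responses was tested by permuting temperature labels within each treatment, over all relabellings.

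On simulated counts for the 24 °C LPS comparison over 17841 genes, edgeR recovered 41% of 100 genes changed 2-fold and 91% of 100 genes changed 4-fold. It called 4 unchanged genes in that comparison and 0 genes in a comparison with no change. DESeq2 1.42.0 recovered 54% and 96% and called 23 unchanged genes, and limma voom recovered 46% and 93% and called 4. The simulation used dispersions estimated by edgeR. Genes were drawn independently and no library was made to stand apart, so these rates may not hold for the real libraries. Totals of 14840723 to 23401031 counts per library set the counting precision. No pair of libraries within a group agreed within sampling noise (lowest chi-square per degree of freedom 34.1 over 60 pairs). Alternatives were DESeq2 size factors, TMM without erythroid and abundant genes, no filter, a stricter filter (1 CPM in 5 samples), DESeq2 1.42.0, limma voom with quality weights, a non-robust fit, fits of only the groups compared, each library left out and the replicate number as a block. Those added after seeing the data left out 3 libraries, added acinar pancreas transcripts as a covariate, matched lists by paralog stem, or used other score genes.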

Results

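The series measured messenger RNA in the spleen of adult zebrafish, a blood-filtering and immune organ, by sequencing of polyadenylated RNA. Embryos and larvae were kept at 24, 28 or 32 °C, all adults were held at 28 °C, and fish of each incubation temperature were either controls or received an intraperitoneal dose of lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria that triggers innate immunity, from Pseudomonas aeruginosa. LPS fish received 2 µl at 50 mg/ml and were sampled 12 h later, at an age of 100 days. The labels do not say what the control fish received, the sex of the fish or the hour of sampling. There were 6 groups of 5 libraries, with replicates numbered as separate samples of a group. That each came from a separate fish is taken from the labels' numbering, so p-values measure the spread between these samples. Library totals ranged from 14840723 to 23401031 counts. Haemoglobin genes led the libraries: hbaa1 (ENSDARG00000097011) took 5.18% ± 2.32 of the counts (SD, n = 30), HBE1 (ENSDARG00000089087) 5.07% ± 2.33 and si:ch211-5k11.8 (ENSDARG00000079078) 4.53% ± 2.09. Globin copies are near-identical, so their separate values are uncertain.

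Some libraries held transcripts of neighbouring organs. Marker sums are given in CPM relative to the total counts of the library, without the TMM scaling used for single genes. In 24 °C control replicate 4 the ovary markers summed to 11182 CPM, against 31.2 to 55.0 CPM in the other 4 fish of its group. Acinar pancreas markers summed to 60693 CPM in that library. In 32 °C control replicate 8 the liver markers summed to 11453 CPM, against 263 to 749 CPM in the other 4. Acinar pancreas markers ranged from 237 to 60693 CPM over all 30 libraries. In 32 °C control replicate 2, 28134 genes had at least 1 count, against 19367 to 22887 in the other libraries.

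**Figure D1:**
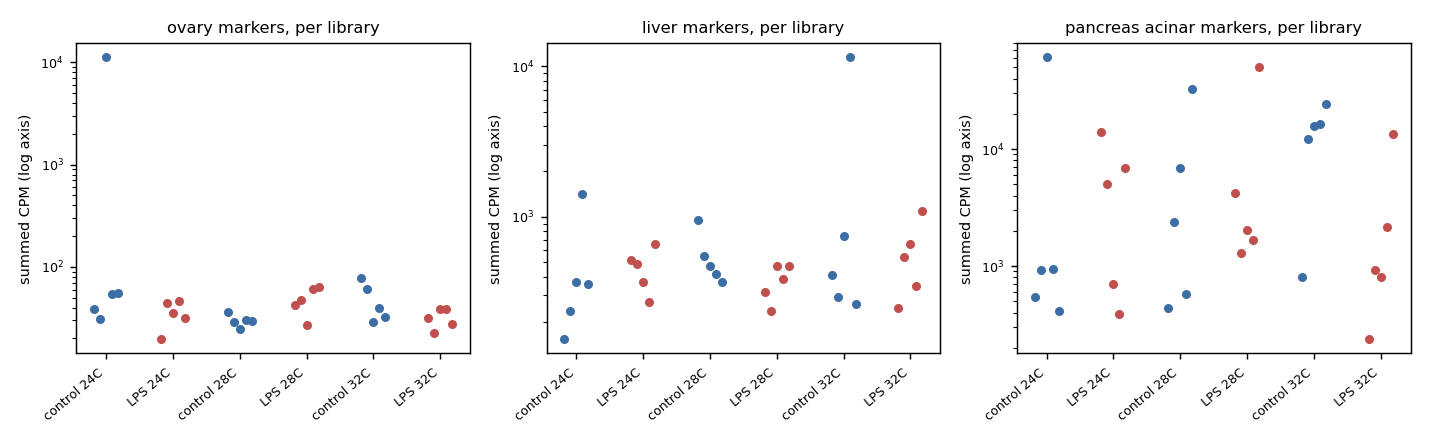
Summed CPM, without TMM scaling, of ovary, liver and acinar pancreas markers in each library, on log axes, by group. Controls are blue, LPS fish are red, and each point is 1 library. The highest ovary value is 11182 CPM in 24 °C control replicate 4 and the highest liver value is 11453 CPM in 32 °C control replicate 8.

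The first comparison asks how the spleen differed between LPS and control fish of each incubation temperature. PER2 (ENSDARG00000034503), a clock repressor that light induces in zebrafish, was higher in LPS fish at all 3 temperatures. Its mean was 57.6 ± 9.78 CPM in LPS fish against 23.7 ± 4.89 in controls at 24 °C (SD, n = 5 each), 77.4 ± 20.8 against 30.5 ± 9.81 at 28 °C, and 82.3 ± 23.5 against 28.2 ± 5.04 at 32 °C. The log2 fold changes were 1.28 ± 0.22 (SE, adjusted p = 0.0257), 1.34 ± 0.22 (adjusted p = 0.0158) and 1.55 ± 0.22 (adjusted p = 0.00261), and the LPS and control fish did not overlap at any temperature. In fits of only the 10 libraries of a temperature the fold changes were 1.29, 1.33 and 1.55, and PER2 did not pass the threshold at any of the 3 temperatures. At 28 °C the call was also lost without any 1 of control replicates 1, 2, 3 and 7 or LPS replicates 1 and 4 (1.203 to 1.36), and at 24 °C without LPS replicate 4 (1.28). It was lost at 24 and 32 °C without the 3 libraries that stood apart (1.29 and 1.43). With the replicate number as a block it was lost at 28 and 32 °C (1.29 and 1.69). PER2's call on the average over the temperatures held in these leave-outs and without the 3 libraries. At 24 °C the other called genes were TAGAP (ENSDARG00000043475) at 1.57 ± 0.28 (adjusted p = 0.0257), and RASGEF1B (ENSDARG00000033614), a Ras exchange factor, at 1.42 ± 0.22 (adjusted p = 0.0149). At 28 °C the second called gene was si:ch211-283g2.5 (138.5 ± 34.5 CPM in LPS fish against 47.0 ± 12.7 in controls), a clone name outside the naming rule and named after its value was seen. Averaged over the temperatures, PER2 (1.39 ± 0.13, adjusted p = 2.67e-07) and CRY1 (ENSDARG00000045768), another clock repressor (0.95 ± 0.14, adjusted p = 0.00123), were called. CRY1 did not pass at any single temperature (adjusted p = 0.0539, 0.108 and 0.559 at 24, 28 and 32 °C). With the replicate number as a block, its call on the average was lost as well (log2 fold change 0.87).

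**Figure D2:**
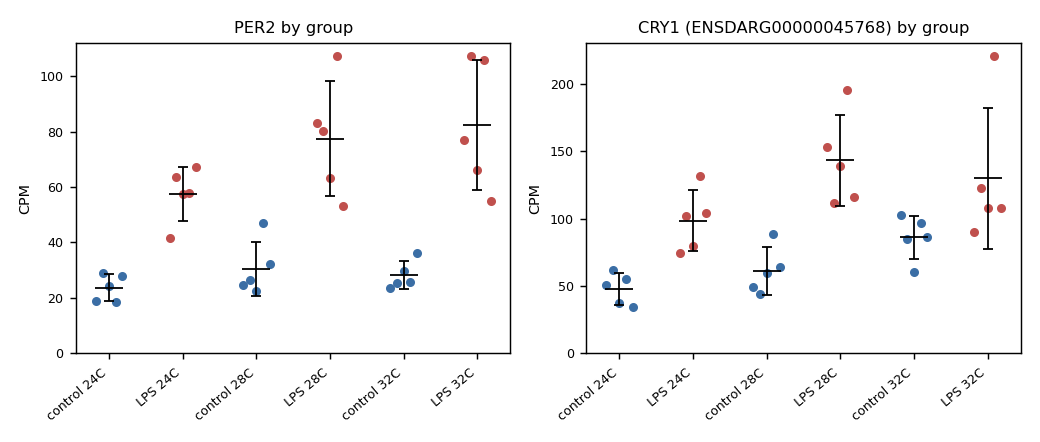
PER2 and CRY1 in CPM by group (points, 1 library each; black dash and bars, mean ± SD, n = 5; blue, control; red, LPS). PER2 means were 23.7, 30.5 and 28.2 CPM in control fish and 57.6, 77.4 and 82.3 CPM in LPS fish at 24, 28 and 32 °C.

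Among 17841 genes tested with edgeR's quasi-likelihood test, 3 genes passed the threshold at 24 °C, 2 at 28 °C, 1 at 32 °C and 2 on average, all higher with LPS. At an unadjusted p under 0.05 there were 3012, 1462, 1314 and 1076 genes, where 892 are expected with no effect. PER2 was the only gene called at all 3 temperatures. For each pair of temperatures, 1 gene was shared, where independent lists of those sizes would share 3.36e-04, 1.68e-04 and 1.12e-04 genes (24 with 28 °C, 24 with 32 °C, 28 with 32 °C). The 24 °C count was 274 with DESeq2, 292, 154, 286 and 283 without 24 °C control replicates 2, 3, 5 and 8, and 0 without 24 °C LPS replicate 4. The 28 °C count was 69 with DESeq2 and 0 without 28 °C control replicates 2, 3 or 7 or LPS replicates 1 or 4, and the 32 °C count was 17 with DESeq2 and 7 without 32 °C control replicate 6. In a fit of only the 32 °C libraries 1 gene passed, lower with LPS, and it was not PER2.

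At 24 °C the 43 measured cytokine and chemokine transcripts rose with LPS as a list under camera's preset correlation (median log2 fold change 0.79, 38 of 43 above 0, camera adjusted p = 4.66e-10), a call lost with an estimated correlation (adjusted p = 0.0759). No member was called over all genes and 4 were called higher adjusted over the list alone. cxcl8a (ENSDARG00000104795), a neutrophil-attracting chemokine, had 73.6 ± 32.3 CPM in LPS fish and 24.95 ± 12.1 in controls (log2 fold change 1.56 ± 0.50, adjusted p = 0.125). At 28 °C the list fell with LPS (median -0.54, camera adjusted p = 6.84e-07), a call also lost with an estimated correlation (adjusted p = 0.192), and 4 members were called lower adjusted over the list alone. Here cxcl8a had 40.2 ± 19.8 CPM in LPS fish and 132 ± 78.1 in controls (-1.71 ± 0.50, adjusted p = 0.354). At 32 °C the list did not pass (median 0.27, 26 of 43 above 0, camera adjusted p = 0.108; adjusted p = 0.528 with an estimated correlation). At 24 °C mitochondrially encoded genes (median 0.28, camera adjusted p = 0.00946), stromal, endothelial and adipose markers (median 0.28, camera adjusted p = 0.00267) and ribosomal protein genes (median 0.24, 80 of 82 above 0) also had higher values with LPS. With an estimated correlation their adjusted p was 0.583, 0.474 and 0.547, and the first pair lost their calls without 24 °C control replicate 4 (adjusted p = 0.136 and 0.115). Erythroid genes moved in the opposite sense to the cytokine list at 24 and 28 °C (35 members, 0 called over all genes and 0 adjusted over the list alone at each of the 3 temperatures). Erythroid genes fell with LPS at 24 °C (median -0.61, camera adjusted p = 9.01e-07; adjusted p = 0.474 with an estimated correlation) and rose at 28 °C (median 0.53, camera adjusted p = 3.08e-08; adjusted p = 0.526 with an estimated correlation). At 32 °C they rose as well (median 0.35, camera adjusted p = 7.83e-05; adjusted p = 0.454 with an estimated correlation).

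B cell and plasma cell markers rose with LPS at 28 °C (21 members, median 0.70, camera adjusted p = 5.28e-04; adjusted p = 0.526 with an estimated correlation) and fell at 32 °C (median -1.05, camera adjusted p = 1.14e-10; adjusted p = 0.209 with an estimated correlation). At each of these temperatures 4 members were called adjusted over the list alone and 0 over all genes with edgeR. At 32 °C, T and NK cell markers (38 members, median -0.49, camera adjusted p = 2.43e-05) and the MHC and antigen presentation list (21 members, median -0.39, camera adjusted p = 3.50e-04) fell too, with adjusted p = 0.352 and 0.270 with an estimated correlation. Markers of other organs moved in the same 32 °C comparison. Acinar pancreas markers fell (27 members, median -1.76, camera adjusted p = 1.65e-08; adjusted p = 0.402 with an estimated correlation), with a median sum of 15638 CPM in controls and 926 in LPS fish. Endocrine pancreas markers fell (8 members, median -2.89, camera adjusted p = 0.00120; adjusted p = 0.352 with an estimated correlation). Mitochondrially encoded genes rose (13 of 13 above 0, median 0.61, camera adjusted p = 1.65e-08; adjusted p = 0.352 with an estimated correlation). With a pancreas covariate, added after seeing the data, the 32 °C count was 17. Neither the T and NK cell list nor the MHC list was called at 28 °C (camera adjusted p = 0.114 and 0.708). Neutrophil markers rose with LPS at 24 °C (27 members, median 0.40, camera adjusted p = 3.66e-06; adjusted p = 0.474 with an estimated correlation), fell at 28 °C (median -0.50, camera adjusted p = 4.45e-07; adjusted p = 0.442 with an estimated correlation) and rose at 32 °C (median 0.42, camera adjusted p = 9.64e-06; adjusted p = 0.352 with an estimated correlation). The neutrophil call at 32 °C was lost without the 3 libraries that stood apart (adjusted p = 0.0593). Complement genes rose at 28 °C (30 members, median 0.48, camera adjusted p = 0.00668; adjusted p = 0.590 with an estimated correlation). Liver markers had fold changes above 0 there in 35 of 36 members (median 2.54, camera adjusted p = 2.86e-08; adjusted p = 0.542 with an estimated correlation), while their summed CPM was lower in LPS fish (group median 383 CPM against 468 in controls). At 32 °C complement genes fell (median -1.02, camera adjusted p = 5.07e-04; adjusted p = 0.361 with an estimated correlation). The complement call at 32 °C was lost without the 3 libraries with other-organ transcripts or many more detected genes (adjusted p = 0.562), a set chosen after seeing the data, and liver markers were not called there (median -2.04, camera adjusted p = 0.0907). Cell cycle and ovary lists fell at 24 °C with camera and also lost their calls without those libraries (adjusted p = 0.131 and 0.431). With an estimated correlation the adjusted p of each was 0.474.

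The second comparison asks whether the LPS response differed between incubation temperatures. Between 24 and 28 °C, 134 genes differed in response, 104 with a higher and 30 with a lower value at 24 °C. The gene with the smallest p was RASGEF1B, whose response differed by 2.44 ± 0.32 on the log2 scale (adjusted p = 3.87e-04): its mean went from 72.8 ± 11.4 CPM in controls to 194 ± 40.03 in LPS fish at 24 °C, and from 233 ± 25.8 to 114 ± 33.0 at 28 °C. ALCAM (ENSDARG00000026531), a leukocyte adhesion molecule, differed by 2.82 ± 0.44 (adjusted p = 0.00475). PIKFYVE, a lipid kinase of endosomes (1.602 ± 0.29), SLC30A1, a zinc exporter (1.87 ± 0.35), and the transcription factor ets2 (1.80 ± 0.34) each had an adjusted p of 0.0224. The remaining genes of the 10 smallest p values were sowahd, sema4ab, ITPKC, tuft1a and SMURF1, with differences from 1.36 to 1.98.

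The cytokine and chemokine list differed in response between 24 and 28 °C (median difference 1.34, camera adjusted p = 6.06e-11), with 5 of 43 members called over all genes and 21 adjusted over the list alone. This call held with an estimated correlation (adjusted p = 0.0393). The responses had opposite signs, and the controls were further apart (mean log2 CPM of the list 2.38 at 24 °C and 3.397 at 28 °C) than the LPS fish (3.15 and 2.67). Erythroid genes differed the other way (median -1.23, 0 called over all genes and 5 lower adjusted over the list alone, camera adjusted p = 5.20e-10; adjusted p = 0.474 with an estimated correlation). cxcl8a differed by 3.27 ± 0.71 (adjusted p = 0.0343) and NCF4, an NADPH oxidase subunit of phagocytes, by 1.53 ± 0.31 (adjusted p = 0.0247). The count of 134 fell to 3 without 28 °C LPS replicate 1, rose to 446 without 28 °C LPS replicate 2, and changed by over 1.5 times in 19 of 30 such leave-outs. DESeq2 gave 815 genes.

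Between 32 and 28 °C, 20 genes differed in response, 4 higher and 16 lower at 32 °C. The lower ones included the antigen presentation genes cd74a (ENSDARG00000009087; -3.13 ± 0.52, adjusted p = 0.0154) and cd74b (-2.70 ± 0.49, adjusted p = 0.0159), the B cell receptor component cd79a (-3.399 ± 0.60, adjusted p = 0.0159) and the complement genes c1qa, c1qb and c1qc (-2.37, -1.98 and -2.03). cd74a went from 1314 ± 874 CPM in controls to 369 ± 74.8 in LPS fish at 32 °C and from 255 ± 80.9 to 629 ± 144 at 28 °C. ALCAM (2.71 ± 0.44, adjusted p = 0.0154) and the TNF receptor family member tnfrsf9a (3.099 ± 0.58, adjusted p = 0.0211) were higher. The other named genes were ms4a17a.10 (-2.36) and SLC7A9 (-4.16). B cell and plasma cell markers fell as a list (median -1.85, camera adjusted p = 3.90e-11; adjusted p = 0.0821 with an estimated correlation), with 2 members called over all genes and 8 adjusted over the list alone. Liver markers (median -4.23, camera adjusted p = 1.03e-06; adjusted p = 0.453 with an estimated correlation, and 0.810 without the 3 libraries that stood apart) and acinar pancreas markers (median -2.11, camera adjusted p = 8.79e-06; adjusted p = 0.458 with an estimated correlation) fell in the same comparison. The count was 5 without 28 °C control replicate 2, 52 without 32 °C control replicate 6, 0 in a fit of only these 4 groups and 146 with DESeq2.

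Between 32 and 24 °C, 4 genes differed, all lower at 32 °C: RASGEF1B (-2.25 ± 0.32, adjusted p = 0.00169), TAGAP (-2.47 ± 0.39, adjusted p = 0.00606) and the clock genes PER1 (ENSDARG00000056885; -2.95 ± 0.47, adjusted p = 0.00606) and BHLHE40 (ENSDARG00000004060; -1.29 ± 0.23, adjusted p = 0.0310). PER1 went from 18.4 ± 4.19 to 38.8 ± 8.23 CPM at 24 °C and from 58.4 ± 23.9 to 15.9 ± 2.29 at 32 °C. NR1D1, cited4a, IP6K2, ITPKC and il34 had the next smallest p values and did not pass (adjusted p from 0.0703 to 0.169). The count was 0 without the 3 libraries that stood apart and 39 with DESeq2. A joint test for any difference between temperatures called 65 genes.

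Across genes, LPS fold changes at 24 and 28 °C were inversely related (Pearson r = -0.226, Spearman rho = -0.325, 36.5% of genes with the same sign), those at 28 and 32 °C less so (r = -0.161, rho = -0.117) and those at 24 and 32 °C positively (r = 0.185, rho = 0.181). The fold changes set against each other in a pair share no libraries, and genes are not independent replicates, so no p is given. A score was built from the genes called in a fit of only the 10 libraries of the temperature left out of a comparison, and compared by permuting temperature labels within treatment. It could use 1 gene (24 against 28 °C; difference of responses -0.82, exact two-sided permutation p = 0.472 over 63504 relabellings), 3 genes (32 against 28 °C; 0.40, exact permutation p = 0.636) and 0 genes for 32 against 24 °C. The mean log2 CPM of the cytokine list, a score chosen after seeing the data, differed in response by 1.49 between 24 and 28 °C (exact two-sided permutation p = 0.00142), by 0.91 between 32 and 28 °C (exact permutation p = 0.0196) and by -0.59 between 32 and 24 °C (exact permutation p = 0.0659).

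**Figure D3:**
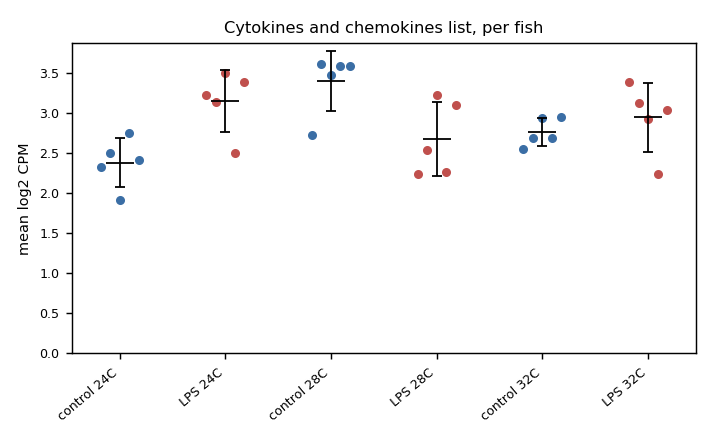
Mean log2 CPM of the 43 cytokine and chemokine genes in each fish by group (points, 1 library each; black dash and bars, mean ± SD, n = 5; blue, control; red, LPS). Control means were 2.38, 3.397 and 2.76, and LPS means 3.15, 2.67 and 2.94, at 24, 28 and 32 °C.

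The third comparison asks how control fish differed by incubation temperature. Several inflammatory transcripts were higher in controls incubated at 28 °C. cxcl8a had 132 ± 78.1 CPM at 28 °C, 24.95 ± 12.1 at 24 °C (log2 fold change -2.40 ± 0.51, adjusted p = 0.0269) and 24.0 ± 5.95 at 32 °C (-2.45 ± 0.52, adjusted p = 0.0287). The acute phase gene SAA2 had 400 ± 229 CPM at 28 °C and 45.5 ± 42.1 at 24 °C (-3.14 ± 0.73, adjusted p = 0.0279), and the chemokine cxcl11.1 had 89.3 ± 67.4 and 8.15 ± 5.60 (-3.45 ± 0.80, adjusted p = 0.0280). These 24 against 28 °C calls were lost, with the direction kept, without 24 °C control replicate 4 and without any 1 of 28 °C control replicates 2, 3 and 7. Of the 165 genes called lower at 24 °C, 5 stayed called without 24 °C control replicate 4, while their median log2 fold change was -1.16 with it and -1.13 without. The CXCL8 receptor gene cxcr1 was lower at 32 than at 28 °C (-3.50 ± 0.62, adjusted p = 0.0146), as were LECT2 (ENSDARG00000033227; -2.07 ± 0.50), tnfrsf9a (-1.92 ± 0.42), hhla2a.1, f11r.1 and dennd3b. These 32 against 28 °C calls were lost, with the direction kept, in a fit of only these groups and without the 3 libraries that stood apart, and all but that of cxcr1 were lost without 28 °C control replicate 3.

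As a list, cytokines and chemokines were lower in 24 than in 28 °C controls (median -0.89, 6 of 43 called lower over all genes and 16 adjusted over the list alone, camera adjusted p = 9.23e-12), which held with an estimated correlation (adjusted p = 0.0378). Cytokines and chemokines were also lower in 32 than in 28 °C controls (median -0.55, 1 called lower over all genes and 11 adjusted over the list alone, camera adjusted p = 1.74e-04), a call lost with an estimated correlation (adjusted p = 0.233). Liver markers had a median log2 fold change of 2.94 for 24 against 28 °C controls (camera adjusted p = 5.86e-04; adjusted p = 0.640 with an estimated correlation), a call lost without 24 °C control replicate 5 (adjusted p = 0.0862). Their sum reached 1408 CPM in that library, and its group median was 356 CPM at 24 °C and 468 at 28 °C. Erythroid genes were higher in 24 than in 28 °C controls (median 0.48, 1 of 35 called over all genes and 1 adjusted over the list alone, camera adjusted p = 4.03e-05; adjusted p = 0.548 with an estimated correlation) and were not called between 32 and 28 °C controls (camera adjusted p = 0.680). The acute phase and antimicrobial list, which does not hold SAA2 under that symbol, was not called in either comparison. For 24 against 28 °C its median was 0.19 and its mean 1.00 while camera's direction was down (adjusted p = 0.203; 1 of 22 called higher and 2 lower over all genes, 3 and 5 adjusted over the list alone), and for 32 against 28 °C its median was 1.29 (adjusted p = 0.907; 0 called over all genes, 9 higher and 4 lower adjusted over the list alone). Neutrophil markers were lower at 24 °C (median -0.84, 6 of 27 called, 12 adjusted over the list alone; adjusted p = 0.178 with an estimated correlation) and at 32 °C (median -0.93, 2 called, 14 adjusted over the list alone; adjusted p = 0.118 with an estimated correlation), with NCF4 and cxcr1 called in both. B cell and plasma cell markers were higher at 32 than at 28 °C (median 1.09, 2 of 21 called higher, 8 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation), among them cd79a (2.31 ± 0.43, adjusted p = 0.0168) and the immunoglobulin gene ighm (2.199 ± 0.46, adjusted p = 0.0284). Liver markers (35 of 36 above 0, median 5.51, camera adjusted p = 1.06e-07; adjusted p = 0.589 with an estimated correlation) and acinar pancreas markers (25 of 27 above 0, median 0.51, camera adjusted p = 0.0121; adjusted p = 0.764 with an estimated correlation) had higher fitted values in the same comparison. The liver sum was 11453 CPM in 32 °C control replicate 8 alone, its group median was 412 CPM at 32 °C against 468 at 28 °C, and the liver call was lost without the 3 libraries that stood apart (adjusted p = 0.124). The glycolysis and hypoxia list was lower at 32 than at 28 °C (median -0.50, mean -0.13, 0 of 22 called over all genes and 8 lower adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.0398). FKBP5 (ENSDARG00000028396), a glucocorticoid-responsive chaperone gene, had 22.4 ± 5.96 CPM in 24 °C controls and 468 ± 369 in 28 °C controls (-4.38 ± 1.06, adjusted p = 0.0307). GDA, batf2, illr4 (-2.65 ± 0.59) and CD180, a Toll-like receptor family member (-2.64 ± 0.59), were also lower at 24 °C. SERPINB1 (ENSDARG00000070396) had 6.81 ± 5.51 CPM in 28 °C controls, 0.0401 ± 0.0228 at 24 °C and 0.138 ± 0.226 at 32 °C. Its level in LPS fish was alike at 28 °C (6.80 ± 5.52 CPM), with 0.0677 ± 0.0472 at 24 °C and 1.25 ± 2.25 at 32 °C, unlike that of cxcl8a. The 24 °C calls of FKBP5, GDA, batf2, illr4, CD180 and SERPINB1 were lost in the same leave-outs.

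**Figure D4:**
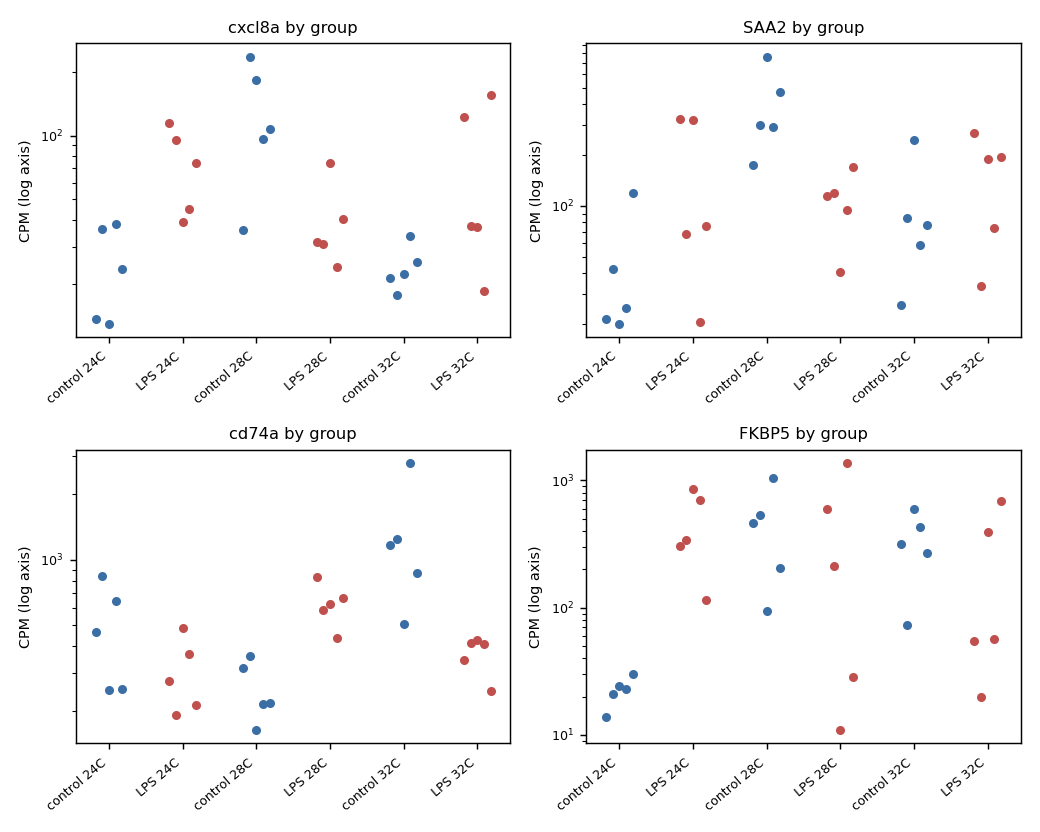
cxcl8a, SAA2, cd74a and FKBP5 in CPM on log axes (each point is 1 library; blue, control; red, LPS). Mean cxcl8a was 132 CPM in 28 °C controls and 24.95 and 24.0 CPM in 24 and 32 °C controls, and mean FKBP5 was 22.4 CPM in 24 °C controls.

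In all, 440 genes differed between 24 and 28 °C controls (275 higher and 165 lower at 24 °C), 113 between 32 and 28 °C controls (75 higher and 38 lower at 32 °C) and 4 between 32 and 24 °C controls. The largest changes at 24 °C were egg and ovary transcripts such as zp3a.2 (188 ± 420 CPM against 0.253 ± 0.287 at 28 °C) and zpax1 (341 ± 760 against 0.813 ± 0.583), carried by 24 °C control replicate 4. retsatl, crp3, CCNA1, epcam, NTN4 and CPEB1 were the other genes named as higher. Cell cycle genes were higher at 24 than at 28 °C (72 members, median 1.24, 23 called over all genes, 61 adjusted over the list alone; adjusted p = 0.472 with an estimated correlation), and ovary markers were too (median 4.42, 4 of 7 called, 7 adjusted over the list alone; adjusted p = 0.548 with an estimated correlation). Without that library 7 genes differed between 24 and 28 °C controls, and 233 of the 275 higher genes had their highest CPM in it. The median log2 fold change of these 275 was 2.62 with it and 0.53 without. The count was also 7 without 28 °C control replicate 2, 13 without replicate 3 and 5 without replicate 7 of 28 °C controls, and 12 with limma voom. In the fit of all libraries, the liver gene uox and apoeb were among those named as higher at 32 than at 28 °C (6.49 ± 1.57 and 4.30 ± 0.69). The others were GRIA3, SLC7A9, NOG, shisa10.2, igldcp and nog2 (2.43 to 3.06). uox had 27.7 CPM in 32 °C control replicate 8, where its group mean was 5.94 ± 12.2. Without the 3 libraries that stood apart, 2 genes differed between 32 and 28 °C controls. That count was 4 without 28 °C control replicate 3 and 506 without 32 °C control replicate 6. Between 32 and 24 °C controls the genes were TAGAP (1.61 ± 0.28), RASGEF1B (1.55 ± 0.23), IP6K2 (ENSDARG00000019613; 0.95 ± 0.16) and BHLHE40 (0.90 ± 0.17), all higher at 32 °C. That count was 0 without the 3 libraries and 97 without 24 °C control replicate 5.

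Among LPS fish, edgeR called 0 genes for 24 against 28 °C, 0 for 32 against 28 °C and 0 for 32 against 24 °C. At an unadjusted p under 0.05 there were 1594, 732 and 754 genes, with 892 expected by chance. DESeq2 called 15, 5 and 5, and limma voom 0, 0 and 0. Cytokines and chemokines were higher at 24 than at 28 °C as a list (median 0.40, 32 of 43 above 0, 0 called over all genes and 0 adjusted over the list alone, camera adjusted p = 0.00156; adjusted p = 0.670 with an estimated correlation). cxcl8a had 73.6 ± 32.3, 40.2 ± 19.8 and 73.9 ± 60.4 CPM in LPS fish of 24, 28 and 32 °C.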

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

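All tests of explanations in this part were chosen after the results were seen. The tests of other groupings of the fish were planned before. Library measures and named genes were checked within each group, in 378 sets of 5 values, and 35 sets held a value far from the other 4. About 18.9 would be expected if the sets were independent and normally distributed. The sets reuse the same 6 groups, and some genes were named from calls that such libraries carried. The excess over 18.9 is therefore no measure against chance.

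The count of genes whose LPS response differed was 134 between 24 and 28 °C, 20 between 32 and 28 °C, 4 between 32 and 24 °C and 65 in the joint test. Cytokine and chemokine transcripts were higher as a list in 28 °C than in 24 °C controls, and than in 32 °C controls only with the preset correlation (adjusted p = 0.233 with an estimated correlation), and with LPS at 28 °C their median was -0.54. A single 28 °C control fish is argued against: the cytokine score of 28 °C controls exceeded that of the other controls by 0.83 ± 0.20 (SE), and by at least 0.77 ± 0.23 with any of the 5 fish left out. A lower erythroid share alone would raise neutrophil and B cell markers alike. In 28 °C controls neutrophil markers were higher (0.94 ± 0.21) and B cell markers lower (-0.86 ± 0.31) than in the other controls, a difference of 1.80 ± 0.45. Both lists had been seen to move apart in these controls before they were chosen. Their difference therefore describes these lists and cannot decide on the erythroid share for the cytokine transcripts. An exchange of the control and LPS labels at 28 °C cannot be told apart from a real difference. PER2 kept its direction at 28 °C (1.34 ± 0.22), as did CRY1 (1.23 ± 0.24, not past the threshold there). Of 10 genes with a shared sign and unadjusted p under 0.01 at 24 and 32 °C, however, only 2 kept theirs at 28 °C. PER2 was 1 of these 2, so it enters both sides of this comparison. Incubation temperature stays open, untested against holding or sampling of each group.

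PER2 was called higher in LPS fish at each temperature, and CRY1 on average over the temperatures only. Different light exposure before sampling may account for this: the light-induced DNA repair genes DDB2 (0.69 ± 0.23), NEIL1 (0.37 ± 0.15) and XPC (0.24 ± 0.15) had a median log2 fold change of 0.37, though none passed the threshold over all genes. tefa was first part of this list and was left out because its value was already known (median 0.45 with it). PER1 cannot decide on a clock shift shared by the 3 temperatures, since it was picked after its difference in response had been called. Its response was 1.08 at 24 °C, -0.72 at 28 °C and -1.87 at 32 °C (32 minus 24 °C, -2.95 ± 0.47). Without the 3 libraries that stood apart 0 genes were called, and PER1's difference had a smaller size and a larger SE (-2.48 ± 0.51, adjusted p = 0.184). An effect of LPS on these genes stays open, since treatment and hour of sampling are not separated by the labels.

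The genes called higher in 24 °C than in 28 °C controls may reflect ovary tissue in 24 °C control replicate 4. Of the 275 genes, 233 peaked in that library. The median log2 fold change of the 275 was 2.62 with it, 0.53 without it and 2.504 to 2.80 without any other of the 24 and 28 °C controls. Without it 241 of them were still above 0. That library also held acinar pancreas markers at 60693 CPM, so leaving it out cannot single out ovary tissue. The loss of calls without that library is not particular to these genes, since 1 of the 275 and 5 of the 165 called lower stayed called, and the lower genes kept their median (-1.16 and -1.13).

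Permuting treatment labels within each temperature (50 splits, the real one included) gave as many genes as the real split in 1 split at 24 °C (3 genes; highest other 2), 3 at 28 °C (2; 216), 2 at 32 °C (1; 1) and 3 on average (2; 565). The limit set beforehand for the share of such splits was kept at 24 and 32 °C, and not at 28 °C or on average. Temperature labels were also permuted within control and within LPS fish (50 splits). This gave as many in 2 splits for the response at 24 against 28 °C (134, highest other 185) and 1 for 32 against 28 °C (20, highest other 0). It gave 2 for 32 against 24 °C (4, highest other 417) and 1 for the joint test (65, highest other 20). All of these kept the limit, though another split exceeded the real count for 24 against 28 and for 32 against 24 °C. For controls it gave 1 split for 24 against 28 °C (440, highest other 317), which kept the limit. It gave 3 splits for 32 against 28 °C (113, highest other 160) and 3 for 32 against 24 °C (4, highest other 389), which did not. For LPS fish, with 0 genes called, all 50 splits gave as many (highest other 0, 1 and 911). With only 50 splits and no adjustment over the comparisons, a kept limit does not exclude chance. Single splits that called several times the real count point to a structure of the samples, whose nature was not tested. A kept limit therefore does not show that incubation temperature or LPS is the source of a count.

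Single libraries lay far from their group in the following measures. Genes detected numbered 22887 in 24 °C control replicate 4 and 28134 in 32 °C control replicate 2, which had 15586276 counts. Acinar pancreas markers reached 60693 CPM in 24 °C control replicate 4, 32907 in 28 °C control replicate 7, 50469 in 28 °C LPS replicate 8 and 13390 in 32 °C LPS replicate 5. Liver markers reached 1408 CPM in 24 °C control replicate 5 and 11453 in 32 °C control replicate 8, and ovary markers 11182 in 24 °C control replicate 4. In 24 °C control replicate 4, zp3a.2 had 941 CPM, retsatl 1122, zpax1 1701, CCNA1 541 and epcam 532. In 32 °C control replicate 8, crp3 had 34.3 CPM, uox 27.7 and igldcp 12.1. Among the other 28 °C libraries, crp3 had 0.115 and epcam 1.73 CPM in control replicate 7, SLC7A9 0.113 in control replicate 5, BHLHE40 121.8 in control replicate 2, uox 0.249 in LPS replicate 2, tuft1a 16.5 in LPS replicate 1, and CPEB1 1.36 and SERPINB1 0 in LPS replicate 3. At 24 °C, ALCAM had 54.2 CPM in control replicate 5, SERPINB1 0 in control replicate 2, and epcam 1.44 and NTN4 0.0929 in LPS replicate 1. At 32 °C, sowahd had 50.0 CPM in LPS replicate 4, cd79a 1.01 and igldcp 7.54 in LPS replicate 5, sema4ab 18.9 in control replicate 6 and zp3a.2 0.0585 in control replicate 10.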

How the results depend on the processing

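The alternatives that left out 3 libraries, added the pancreas covariate, matched lists by paralog stem or used other score genes were chosen after seeing the data. DESeq2 size factors and TMM without erythroid and abundant genes kept each count within 1.5 times. Over 2941 refits of 72 pairs of a named gene and a comparison, 2358 kept their side of the threshold and their direction, 546 lost the call, 29 gained it and 8 reversed. Many refits left out a library of a group not compared, which can hardly change the result. Genes that did not pass in the main fit and still did not pass also count as kept. The 2358 are therefore no measure of how stable the calls are. The counts of calls depend on single libraries and on the tool. Totals of 14840723 to 23401031 counts limit mainly genes of few counts, and the common biological coefficient of variation was 0.503. The cause of these changes in count was not tested for any setting.

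With DESeq2, genes past the threshold numbered 274 (LPS at 24 °C), 69 (LPS at 28 °C), 17 (LPS at 32 °C), 4 (LPS on average), 815 (response 24 against 28), 146 (response 32 against 28), 39 (response 32 against 24), 495 (the joint test), 890 (controls 24 against 28), 625 (controls 32 against 28), 300 (controls 32 against 24), 15 (LPS fish 24 against 28), 5 (LPS fish 32 against 28), 5 (LPS fish 32 against 24). With limma voom, genes past the threshold numbered 5 (LPS at 28 °C), 6 (LPS on average), 427 (response 24 against 28), 134 (the joint test), 12 (controls 24 against 28), 0 (controls 32 against 24). With no low-count filter, genes past the threshold numbered 33 (response 24 against 28), 13 (response 32 against 28), 26 (the joint test), 47 (controls 32 against 28). With the stricter filter, genes past the threshold numbered 11 (LPS at 24 °C), 2 (LPS at 32 °C), 223 (response 24 against 28), 7 (response 32 against 24), 9 (controls 32 against 24). With the non-robust fit, genes past the threshold numbered 53 (LPS at 24 °C). With only the groups compared, genes past the threshold numbered 0 (LPS at 28 °C), 226 (response 24 against 28), 0 (response 32 against 28), 41 (controls 24 against 28), 0 (controls 32 against 28), 0 (controls 32 against 24). With the 3 libraries left out, genes past the threshold numbered 0 (LPS at 24 °C), 0 (LPS at 32 °C), 8 (response 32 against 28), 0 (response 32 against 24), 5 (the joint test), 7 (controls 24 against 28), 2 (controls 32 against 28), 0 (controls 32 against 24). With the pancreas covariate, genes past the threshold numbered 4 (LPS at 28 °C), 17 (LPS at 32 °C), 89 (response 32 against 28), 8 (response 32 against 24), 127 (the joint test), 102 (controls 24 against 28), 242 (controls 32 against 28), 8 (controls 32 against 24). The mean of 3 temperatures and the joint test use all groups, so the fit of only the groups compared was not run for them.

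With each library left out in turn, the counts ranged from 0 to 292 (LPS at 24 °C), 0 to 5 (LPS at 28 °C), 1 to 7 (LPS at 32 °C), 2 to 6 (LPS on average), 3 to 446 (response 24 against 28), 5 to 52 (response 32 against 28), 3 to 8 (response 32 against 24), 5 to 160 (the joint test), 5 to 753 (controls 24 against 28), 4 to 506 (controls 32 against 28), 1 to 97 (controls 32 against 24), 0 to 1 (LPS fish 24 against 28), 0 to 0 (LPS fish 32 against 28), 0 to 0 (LPS fish 32 against 24).

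The replicate number as a block gave 24 (LPS at 24 °C), 0 (LPS at 28 °C), 2 (LPS at 32 °C), 1 (LPS on average), 41 (response 32 against 28), 109 (the joint test), 20 (controls 24 against 28), 419 (controls 32 against 28), 10 (controls 32 against 24), 1 (LPS fish 24 against 28). Same-numbered control and LPS samples of a temperature did not deviate together more than others (9 pairs, median r -0.0468 against -0.0212 in other pairs). Their r ran from -0.148 to 0.415, with 4 over 0.1. So few pairs cannot exclude a pairing, and numbers shared across temperatures were not compared. With the block, PER2 lost its calls at 28 and 32 °C and CRY1 its call on average.

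The lists called in the fit of the report numbered 17 (LPS at 24 °C), 16 (LPS at 28 °C), 18 (LPS at 32 °C), 14 (LPS on average), 13 (response 24 against 28), 19 (response 32 against 28), 16 (response 32 against 24), 14 (controls 24 against 28), 14 (controls 32 against 28), 20 (controls 32 against 24), 9 (LPS fish 24 against 28), 12 (LPS fish 32 against 28), 12 (LPS fish 32 against 24). With an estimated correlation, the lists called numbered 0 (LPS at 24 °C), 0 (LPS at 28 °C), 0 (LPS at 32 °C), 0 (LPS on average), 1 (response 24 against 28), 0 (response 32 against 28), 0 (response 32 against 24), 1 (controls 24 against 28), 1 (controls 32 against 28), 0 (controls 32 against 24), 0 (LPS fish 24 against 28), 0 (LPS fish 32 against 28), 0 (LPS fish 32 against 24). With fry, the lists called numbered 1 (LPS at 24 °C), 0 (LPS at 28 °C), 0 (LPS at 32 °C), 0 (LPS on average), 2 (response 24 against 28), 2 (response 32 against 28), 0 (response 32 against 24), 3 (controls 24 against 28), 6 (controls 32 against 28), 0 (controls 32 against 24), 0 (LPS fish 24 against 28), 0 (LPS fish 32 against 28), 0 (LPS fish 32 against 24). With the 3 libraries left out, the lists called numbered 9 (LPS at 24 °C), 9 (LPS on average), 8 (controls 32 against 24). Leaving out each library gave 8 to 18 (LPS at 24 °C), 14 to 18 (LPS at 28 °C), 15 to 20 (LPS at 32 °C), 7 to 14 (LPS on average), 12 to 16 (response 24 against 28), 17 to 21 (response 32 against 28), 12 to 21 (response 32 against 24), 13 to 17 (controls 24 against 28), 11 to 17 (controls 32 against 28), 12 to 20 (controls 32 against 24), 7 to 11 (LPS fish 24 against 28), 9 to 13 (LPS fish 32 against 28), 8 to 16 (LPS fish 32 against 24).

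The reversed genes, of 24 against 28 °C controls, were retsatl (-0.0595 with limma voom, -2.11 without the 3 libraries, -2.16 to 10.64 over leave-outs), CCNA1 (-1.33, -2.19 and -2.21 to 8.94) and epcam (-1.09 without the 3 libraries, -1.13 to 10.78 over leave-outs). Leaving out 24 °C control replicate 4 gave each lowest value. The score difference of -0.82 for 24 against 28 °C was 1.49 with the cytokine list and 0.71 with the 100 smallest p values, and for 32 against 28 °C 0.40 became 0.91 and 1.28, both past the threshold. Leave-outs gave -1.45 to -0.37 and 0.0099 to 0.81. Score settings with 0 genes gave no value. At adjusted p under 0.01, 0 genes in place of 1 were shared by all 3 temperatures.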

Other observations

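Averaged over the temperatures, ribosomal protein genes were slightly higher in LPS fish (82 members, 81 above 0, median log2 fold change 0.17, camera adjusted p = 2.54e-23), as were mitochondrially encoded genes (13 of 13 above 0, median 0.27, camera adjusted p = 8.46e-09). Both calls were lost with an estimated correlation (adjusted p = 0.678 each), and edgeR called 0 of their members over all genes. Without TMM scaling, mean ribosomal protein sums in control and LPS fish were 51724 and 63975 CPM at 24 °C, 62917 and 63227 at 28 °C, and 67000 and 61171 at 32 °C. Mean mitochondrial sums were 26011 and 33441 CPM at 24 °C, 35623 and 31775 at 28 °C, and 35508 and 42117 at 32 °C. These unscaled sums were thus not higher in LPS fish at every temperature. Proteasome genes were lower in 32 than in 28 °C controls (51 members, median -0.47, 1 called over all genes and 16 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation).

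The 16 genes with a haemoglobin symbol took 10.385% ± 2.83 of the counts in 28 °C controls and 19.7% ± 7.48 in 28 °C LPS fish (SD, n = 5). They took 15.7% ± 3.86 and 12.1% ± 4.54 at 24 °C and 14.7% ± 4.45 and 16.4% ± 7.08 at 32 °C. The abundant si:ch211-5k11.8, a clone name, is not among them, so these are shares of a part of the haemoglobin genes. FKBP5 ranged from 10.9 to 1374 CPM in single fish of the other 5 groups, and from 13.7 to 30.2 CPM in 24 °C controls.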
